A study of Ambystoma mexicanum with 5 samples.

How the data were processed

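RNA from whole kidneys of 5 axolotls was sequenced, 1 library per animal, from 3 untreated controls and 2 animals given gentamicin. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were prepared with an NEBNext Ultra RNA kit for Illumina. The submitters' processing notes name CASAVA 2.19, fastp, HISAT2 2.0.5 (an aligner), featureCounts 1.5.0-p3 (a read counter) and DESeq2 1.20.0. The genome build and the strand setting of the counting are not given in the sources used here. Coordinates are those of the deposited tables, whose gene identifiers begin with AMEX60DD, and no coordinates from another build were used. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart.

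The authors deposited 2 tables of 100758 genes, and the names of the tables are exchanged relative to their contents. The table named for FPKM holds raw read counts: 100% of its values are whole numbers and the libraries have different totals. The table named for counts holds FPKM as deposited by the authors. Each of its columns equals the count divided by the gene length and the column total, times 1 factor per library (1.0943, 1.0735 and 1.0453 for the controls, 0.8835 and 0.8387 for gentamicin). These factors multiplied by the TMM factors gave 0.974 to 0.986, and their origin is not given in the sources used here. Gene symbols were taken from the deposited tables, where 26835 genes carried one, 21556 of them with counts. The tables held no rows of totals or unassigned reads.

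Libraries were assigned to groups by their labels. The comparison was gentamicin against control, fitted on the deposited counts with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled with TMM, and a quasi-likelihood model with robust dispersion and the group as its only term was tested with glmQLFTest (two-sided), with Benjamini-Hochberg adjustment over the 22006 genes tested. Genes at an adjusted p under 0.05 were called. CPM values are scaled with TMM and given as mean ± SD over 3 controls and 2 gentamicin libraries. The standard error of a log2 fold change is its size divided by the root of the test's F value. For a gene with 1 to 3 counts in a group, the ratio has an exact 95% binomial interval (Clopper-Pearson), and with 0 counts the bound is taken against 3 counts over the group.

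A total of 29 gene lists, covering nephron segments, injury, nephron formation, proliferation, metabolism, stress and other cell types, were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. The lists were tested with camera from limma 3.58.1 (preset correlation 0.01, two-sided) where at least 5 genes were tested, with Benjamini-Hochberg adjustment over 27 lists. Each gene model with a listed symbol counts as a gene. Of these lists 5 pairs share 1 gene each. The rule named the 10 genes with the largest increase and the 10 with the largest decrease among called genes with a symbol, a mean log2 CPM of at least 1 and no overlap between groups, up to 4 members of each list by p, and 21 genes whatever their values. Some genes that the rule takes are not reported here.

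Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, upper-quartile and total-count scaling, no filter on low counts or a mean CPM of at least 1, the number in the label as a block, removal of genes above 1% of a library, each library left out in turn, at least a 2-fold change, and limma on log2(FPKM + 1) or log2(FPKM + 0.1) of the deposited FPKM (mean FPKM of at least 0.5, or no filter). Lists were also tested with fry, with an estimated correlation and with 1 row per symbol.

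The procedure was tested on simulated data for gentamicin against control. With 200 of 20908 genes changed, 43 of 100 genes changed 2-fold and 85 of 100 changed 4-fold were called, 25 of 153 calls were wrong (16.3%), and 1.03% of unchanged genes had a p under 0.01. A second simulation, added after these results because the share of wrong calls was above the limit first set, changed 6000 of 20731 genes, nearer to the number called here. In it 75.5% of 2-fold and 95.8% of 4-fold changes were called and 180 of 5320 calls were wrong (3.4%). Both simulations changed as many genes up as down, by the same folds. They therefore do not cover wrong calls from an uneven balance of changes. In the first simulation 0 of 20 unchanged lists were called. Its genes were drawn independently of each other, so it does not test lists whose genes are correlated. The libraries held between 13674201 and 16404879 counts.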

Results

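RNA was sequenced from whole kidneys of the axolotl (Ambystoma mexicanum), a salamander, in a group of 3 untreated control animals and a group of 2 animals injured with gentamicin. Gentamicin is an aminoglycoside antibiotic that is filtered by the kidney and taken up by proximal tubule cells, which it damages. The series addresses kidney regeneration, and the comparison asks which genes differ between injured and untreated kidneys. The dose and the interval after treatment are not used here. Each library came from a different axolotl, so edgeR's p-values for single genes measure the spread between animals. Camera's p-values with the preset correlation compare the genes of a list with all other tested genes. They do not measure the spread of a list between animals. The numbers in the labels name control libraries 1, 2 and 3 and gentamicin libraries 1 and 3.

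The count table held 100758 genes, of which 39937 had a count in at least 1 library. The control libraries held 13674201, 15087765 and 14884904 counts, and the gentamicin libraries held 15163723 and 16404879. At these depths 3 counts, the limit that a count of 0 allows, corresponded to between 0.183 and 0.219 CPM (counts scaled to library size) in a library. Intervals and floors cover counting error only. The 10 most abundant genes took 9.73% of counts on average in controls and 5.68% in gentamicin libraries. A ferritin heavy chain gene, FTH1, was the most abundant gene in each control (1.68% to 2.65% of counts), and the cytoskeletal actin ACTG1 in both gentamicin libraries (0.86% each). Genes with mitochondrial names in the annotation took 2.17% and 1.42% of counts on average.

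The libraries separated by group. The first principal component of log2 CPM over the tested genes carried 69.3% of the variance and placed the controls at -79.7, -60.2 and -63.4 and the gentamicin libraries at 104 and 99.4. Spearman correlations between libraries of a group were 0.965 to 0.981, against 0.881 to 0.903 between groups. No pair of libraries was identical: the chi-square per degree of freedom was 14.3 to 20.4 within groups and 134.7 to 170.1 between groups.

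In gentamicin-treated kidneys 65 of 72 proximal tubule genes fell, with a list median 10.8-fold lower, along with 26 of 37 genes of fatty acid oxidation, 40 of 45 of oxidative phosphorylation and 15 of 20 of cholesterol synthesis. Higher genes numbered 20 of 26 for macrophages, 26 of 42 for inflammatory signalling, 51 of 76 for the cell cycle and 23 of 56 for tubular injury. These 8 lists were called by camera with its preset correlation but not with an estimated correlation (smallest adjusted p = 0.113). The list of nephron formation genes was not called in either direction. Of 22006 genes tested, 2931 were higher and 2959 lower after gentamicin at an adjusted p under 0.05 in edgeR's quasi-likelihood test. At least a 2-fold change was seen in 1636 of the higher and 1705 of the lower genes, at least 4-fold in 823 and 869, and at least 16-fold in 133 and 334. Scaled to total counts instead of TMM (trimmed mean of M-values) factors, 6192 genes were higher and 1895 lower, or 76.6% of calls higher against 49.8%. That scaling shifted the median of all genes by 0.32 on the log2 scale, so the changes given here are relative to the TMM scale. Both groups had non-overlapping CPM in 12164 genes (55.3%, against 20% by chance), among them all 5890 called genes. With gentamicin library 1 left out 1333 genes were higher and 1739 lower, and with library 3 left out 1368 and 1627.

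**Figure D1:**
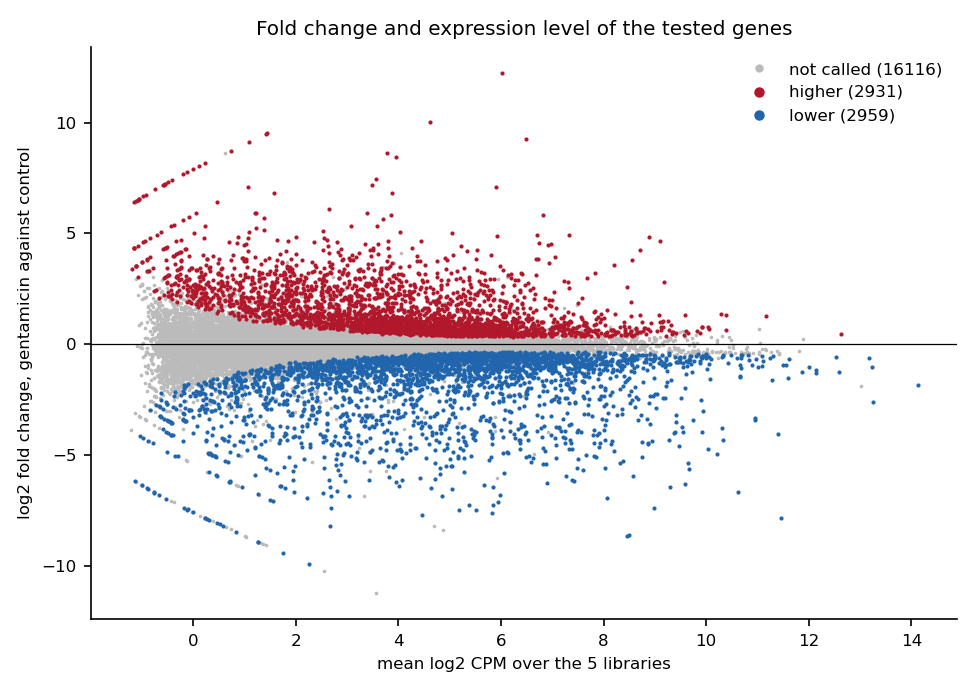
Log2 fold change of gentamicin against control for each of the 22006 tested genes (vertical axis), against mean log2 CPM over the 5 libraries (horizontal axis). Red points are the 2931 genes called higher and blue points the 2959 called lower; the diagonal rows of points at low expression are genes with few or no counts in 1 of the groups, whose fitted fold changes are not bounds.

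Proximal tubule genes, of the segment that reabsorbs most of the filtrate, had the lowest median of the lists tested. Of 72 tested genes, 65 fell and 2 rose, with the same counts adjusted over the list alone. The median gene was 10.8-fold lower, a log2 fold change of -3.43 (camera adjusted p = 9.08e-84; adjusted p = 0.113 with an estimated correlation). LRP2, or megalin, a receptor that takes up filtered proteins and aminoglycosides, fell from 1544 ± 319 to 97.7 ± 8.82 CPM (SD, n = 3 and 2), a log2 fold change of -3.98 ± 0.22 (SE; edgeR adjusted p = 1.04e-05). The LRP2 gene lies on chromosome 9q, 438850011 to 439365239. SLC34A1, the phosphate transporter of the brush border, fell from 1923 ± 387 to 62.3 ± 5.04 CPM, or 30.9-fold (edgeR adjusted p = 4.71e-06; chromosome 3p, 621514494 to 621722991). MIOX, which breaks down inositol in this segment, fell 168-fold, from 836 ± 44.4 to 4.97 ± 0.119 CPM (edgeR adjusted p = 1.37e-06). The anion transporter SLC22A8 fell 47.7-fold and the scaffold protein PDZK1 21.1-fold. CUBN, or cubilin, the partner of megalin, is split over 4 tested gene models that may share reads. The most abundant of these, AMEX60DD022111, fell 22.7-fold, and the others fell 16.5- to 27.3-fold. The genes that rose were FBP1 (1.49-fold) and SLC7A7 (1.48-fold). These, like other members named beside a count of 5 or fewer that the fixed rule had not taken, were chosen after their values were seen. Without gentamicin 1 or gentamicin 3 no gene of the list was called higher, and without control 2 or control 3 the number was 1. The list took 1.87% ± 0.157 of counts in controls and 0.239% ± 0.00608 after gentamicin. Macrophage genes moved the other way, by a median log2 fold change of 2.89.

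Genes of the distal nephron, which adjusts salt, water and acid excretion, were lower by less. Of 45 tested genes, 26 fell and 2 rose (29 and 3 adjusted over the list alone), with a median log2 fold change of -0.88 (camera adjusted p = 8.78e-07; adjusted p = 0.234 with an estimated correlation). CLDN10, a tight junction claudin, fell 21.9-fold from 134 ± 41.6 CPM. SCNN1A, a subunit of the epithelial sodium channel, had 423 counts in controls and 1 after gentamicin, a ratio of 382 (95% counting interval 68.2 to 15130; edgeR adjusted p = 0.000199). SLC12A1, the salt transporter of the diluting segment, fell 1.43-fold from 1465 ± 134 to 1025 ± 56.4 CPM (edgeR adjusted p = 0.0216). It was not called without control 2 (edgeR adjusted p = 0.0579), gentamicin 1 (0.121) or gentamicin 3 (0.0692), nor with total-count scaling (0.27), with the replicate number as a block (0.087) or on unfiltered FPKM (0.0613). The water and glycerol channel AQP3 rose 2.60-fold. UMOD, the urinary protein uromodulin, matched 26 gene models of which 7 were tested, all of them under 5 CPM in controls, and their paralogous sequences leave the counts uncertain. Of these AMEX60DD005631 was called, from 1.26 to 3.98 CPM (edgeR adjusted p = 0.0181), and it was not called without gentamicin 1 (0.0694) or gentamicin 3 (0.184) or on unfiltered FPKM (0.0938). Without control 1 AMEX60DD005673 was called lower and AMEX60DD005735 higher (log2 fold changes of -1.199 and 8.14, edgeR adjusted p = 0.0468 and 0.000999). The proximal tubule list fell with this list.

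Podocyte genes, of the glomerular filter, were not called as a list. Of 28 tested genes 3 rose and 5 fell (4 and 5 adjusted over the list alone), with a median log2 fold change of -0.15 (camera adjusted p = 0.478). NPHS1, or nephrin, had 12.4 ± 1.30 CPM in controls and 17.8 ± 1.88 after gentamicin and did not pass the test (edgeR adjusted p = 0.051). It passed without control 1 (0.0373), with total-count scaling (0.00464), without a filter (0.0386), in limma-voom (0.0485) and in the filtered FPKM fits (0.0421 and 0.0422). WT1 stood at 24.1 ± 2.7 and 20.4 ± 1.46 CPM (edgeR adjusted p = 0.271). Both CLIC5 gene models fell (16.2- and 12.8-fold), as did KIRREL1 and ARHGAP24, and INF2 and 2 SYNPO gene models rose. With gentamicin 1 or gentamicin 3 left out, 3 podocyte genes were lower instead of 5.

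Genes of tubular injury and repair were called up as a list. Of 56 tested genes, 23 rose and 2 fell (30 and 2 adjusted over the list alone), with a median log2 fold change of 0.88 (camera adjusted p = 1.18e-10; adjusted p = 0.113 with an estimated correlation). MMP7, a matrix metalloproteinase, rose 57.2-fold, from 4.79 ± 0.937 to 275 ± 1.48 CPM (edgeR adjusted p = 1.95e-06). The deposited protein description of this gene model is stromelysin-1, so its identity is uncertain. The stress transcription factor ATF3 rose 19.0-fold, the secreted chaperone CLU, or clusterin, 6.94-fold and the cell cycle inhibitor CDKN1A 5.60-fold. VIM, or vimentin, an intermediate filament of mesenchymal and dedifferentiated cells, rose 2.49-fold, from 842 ± 155 to 2097 ± 272 CPM (edgeR adjusted p = 0.000925). SOX9, a transcription factor of regenerating tubules, rose 2.12-fold (edgeR adjusted p = 0.0324), a call that was lost without control 2 (0.0783), gentamicin 1 (0.153) or gentamicin 3 (0.156) and on unfiltered FPKM (0.0872). Osteopontin, SPP1, had 2 neighbouring gene models: AMEX60DD043904 rose 25.7-fold to 50.9 ± 6.52 CPM, while the abundant AMEX60DD043905 stood at 603 ± 117 and 899 ± 155 CPM (edgeR adjusted p = 0.0555). The latter passed without control 1 (0.0202), with total-count scaling (0.005), without a filter (0.00014) and in DESeq2 (0.0199). FGB and CDH6 fell (2.18- and 1.79-fold), and the number of lower genes was 1 without control 3 or gentamicin 3. The injury markers HAVCR1 and LCN2 matched no gene name and were not analysed here. The macrophage list, with which these genes moved, rose by a median of 2.89.

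Immediate early and heat shock genes, which respond to stress within minutes, were called up as a list, some of them from near the floor. Of 17 tested genes 9 rose and 1 fell (10 and 1 adjusted over the list alone), with a median log2 fold change of 0.91 (camera adjusted p = 5.17e-09; adjusted p = 0.113 with an estimated correlation). FOS rose by a log2 fold change of 5.32, from 0.692 ± 0.249 to 28.3 ± 2.61 CPM, EGR3 16.2-fold and JUNB 9.72-fold. Outside the list, EGR4 had 1 count in the 3 controls and 5763 in the gentamicin libraries, a ratio of 6378 (95% counting interval 1144 to 251900; edgeR adjusted p = 1.95e-06; chromosome 6q, 1544653545 to 1544658584). FOSL1 rose from 0.362 ± 0.289 to 221 ± 88.1 CPM and ARC from 0.311 ± 0.249 to 35.2 ± 11.4 CPM. Adjacent heat shock 70 genes named HSPA8 and HSPA1L on chromosome 13q rose from 0.0968 to 37.8 and from 0.148 to 28.2 CPM, but their models overlap and resemble other family members, so the share of each is uncertain. The HSPA8 model AMEX60DD017913, at 274 CPM in controls, was the list's member that fell, by 1.68-fold, and it was not called without gentamicin 3. The macrophage and inflammatory signalling lists rose with this list, by medians of 2.89 and 1.28.

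Inflammatory signalling genes were called up as a list, with exceptions. Of 42 tested genes 26 rose and 4 fell (30 and 4 adjusted over the list alone), with a median log2 fold change of 1.28, also with 2 genes without control counts set to their bounds (camera adjusted p = 1.21e-11; adjusted p = 0.113 with an estimated correlation). IRF1, an interferon-induced transcription factor, rose 29.3-fold, from 4.87 ± 1.46 to 143 ± 22.2 CPM (edgeR adjusted p = 7.92e-06). Gene models named for the neutrophil attractant CXCL8 lie in a cluster on chromosome 6q and may share reads. AMEX60DD044141 had 3 counts in controls and 1197 after gentamicin (ratio 441.5; 95% counting interval 150.7 to 2144), and AMEX60DD044137 and AMEX60DD044139 reached 14.5 and 19.6 CPM. Complement C3 fell 5.05-fold in its abundant model and 3.57-fold in a weak one, and TLR2 and SOCS1 fell 1.40- and 1.71-fold. The number of lower genes in the list was 2 without control 2, 2 without gentamicin 1 and 1 without gentamicin 3. The macrophage list rose with this list.

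Macrophage genes rose most of all immune lists. Of 26 tested genes 20 rose and 2 fell (the same adjusted over the list alone), with a median increase of 7.41-fold, or 2.89 on the log2 scale (camera adjusted p = 2.52e-23; adjusted p = 0.141 with an estimated correlation). The macrophage growth factor receptor CSF1R rose 5.76-fold, from 33.9 ± 6.62 to 195 ± 7.13 CPM (edgeR adjusted p = 2.17e-05). The scavenger receptor MARCO rose 24.1-fold, CD68 14.6-fold, the complement component C1QA 7.95-fold and GPNMB 136-fold from 1.08 ± 0.728 CPM. The deposited protein description of the CD68 model is lysosome-associated membrane glycoprotein 1, so its identity is uncertain. The members that fell were APOE (4148 ± 391 to 1459 ± 268 CPM) and LGMN (1094 ± 141 to 276 ± 2.94 CPM), the list's most abundant genes in controls, which other cell types also express. With these, the list took 0.519% of counts in controls and 0.497% after gentamicin.

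Other blood cell lists moved less than the macrophage list. Granulocyte genes had 9 higher and 1 lower of 17 (10 and 1 adjusted over the list alone) and a median log2 fold change of 1.25 (camera adjusted p = 0.000221; adjusted p = 0.281 with an estimated correlation). The lipoxygenase ALOX5 fell 2.60-fold. B and plasma cell genes had 5 higher and none lower of 10 (5 and 0 adjusted over the list alone), namely CD22, BLNK, CD79B and 2 models of the kinase BTK (median log2 1.45, camera adjusted p = 0.000464; adjusted p = 0.141 with an estimated correlation), and 3 were higher without gentamicin 1. T and NK cell genes were not called as a list (13 tested, 3 higher and 2 higher adjusted over the list alone; median log2 1.26; camera adjusted p = 0.0578). CD3G, LCK and PRF1 were the higher genes, and the number was 0 without gentamicin 1 and 1 without control 2 or control 3; the list was called without gentamicin 3, without a filter on low counts and with the replicate number as a block. Erythroid genes had 3 higher and 3 lower of 27 (2 and 3 adjusted over the list alone) and a median of -0.42 (camera adjusted p = 0.37). RHAG, EPOR and an alpha globin model, HBA1, were higher, the last with 0 control counts and thus at least 28.8-fold higher against a floor of 3 counts over the group. SLC4A1, FECH and EPB41 were lower. The number higher was 1 without control 2 or gentamicin 3, and the number lower was 6 without control 1.

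Cell cycle genes were called up as a list. Of 76 tested genes 51 rose and 1, MCM3, a weakly expressed model, fell (61 and 1 adjusted over the list alone), with a median increase of 1.99-fold, or 0.99 on the log2 scale (camera adjusted p = 2.6e-11; adjusted p = 0.281 with an estimated correlation). Without gentamicin 1 the number higher was 32, without gentamicin 3 it was 18, and MCM3 was not called with control 2, gentamicin 1 or gentamicin 3 left out. The mitotic cyclins CCNA2 and CCNB1 rose 2.76- and 3.42-fold, from 15.8 ± 2.55 to 43.6 ± 2.42 CPM and from 4.25 ± 0.739 to 14.5 ± 2.31 CPM. SMC2, a condensin subunit, rose 2.90-fold and the centromere protein CENPE 2.34-fold. The proliferation marker MKI67 rose 1.48-fold in its abundant model AMEX60DD052733, from 150 ± 14.2 to 222 ± 28.7 CPM (edgeR adjusted p = 0.0157), a call lost without gentamicin 3 (0.147) and on unfiltered FPKM (0.0755). The weak model AMEX60DD028336 stood at 9.66 and 8.28 CPM (edgeR adjusted p = 0.555). Macrophage genes rose with this list.

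Genes that p53 activates after DNA damage were not called as a list. Of 30 tested genes 10 rose and 7 fell (13 and 8 adjusted over the list alone), with a median log2 fold change of 0.4 (camera adjusted p = 0.0662), and the list was called without gentamicin 1, without a filter on low counts and by fry (adjusted p = 0.003). MDM2, the negative regulator of p53, rose 3.14-fold and EDA2R 28.2-fold, while CCNG1 fell 2.30-fold. Without gentamicin 1 there were 5 higher and 2 lower genes, and without gentamicin 3 there were 6 and 3. Cell death genes had 10 higher and none lower of 26 (10 and 0 adjusted over the list alone; median log2 0.27; camera adjusted p = 0.00827; adjusted p = 0.141 with an estimated correlation), and 5 were higher with gentamicin 1 or gentamicin 3 left out. The number of lower cell death genes was 1 without control 1 and 1 without control 2. BCL2L11, a promoter of apoptosis, rose 2.78-fold and the inflammasome adaptor PYCARD 2.64-fold. Macrophage genes rose with this list.

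Nephron formation genes showed no common direction. Of 53 tested genes 5 rose and 7 fell, also adjusted over the list alone, with a median log2 fold change of -0.12 (camera adjusted p = 0.833). The markers of nephron progenitors were low in both groups and did not pass the test: SIX2 had 0.577 ± 0.147 and 0.595 ± 0.253 CPM, and EYA1 0.589 ± 0.300 and 0.617 ± 0.726 CPM (edgeR adjusted p = 0.976 and 0.987). PAX2 stood at 69.3 ± 5.89 and 66.1 ± 2.52 CPM (edgeR adjusted p = 0.725) and LHX1, a gene of new nephrons, at 24.2 ± 1.87 and 18.5 ± 3.41 CPM (edgeR adjusted p = 0.117). DKK1, a secreted Wnt inhibitor, rose 59.9-fold, from 0.401 ± 0.108 to 24.5 ± 4.45 CPM (edgeR adjusted p = 4.48e-06). WNT4, WNT9B, BMP7 and LEF1 rose between 1.69- and 2.15-fold. RET, the receptor of the branching ureteric bud, fell 2.44-fold. Without gentamicin 1 there were 1 higher and 2 lower genes, and without gentamicin 3 there were 2 and 3.

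Extracellular matrix genes were called up as a list, while COL1A1, the main fibrillar collagen, did not pass the test. Of 46 tested genes 18 rose and 3 fell (19 and 4 adjusted over the list alone), with a median log2 fold change of 0.43 (camera adjusted p = 6.6e-05; adjusted p = 0.464 with an estimated correlation). TGFBI rose 8.82-fold, the collagen cross-linking enzyme LOX 7.63-fold and THBS1 2.49-fold. COL1A1 stood at 2372 ± 841 and 2071 ± 63.6 CPM (edgeR adjusted p = 0.646), and ACTA2, smooth muscle actin, at 248 ± 71.5 and 318 ± 141 CPM (edgeR adjusted p = 0.546). FBLN1, FBLN2 and TGFB2 fell. Without gentamicin 1 there were 10 higher and no lower genes, and without gentamicin 3 there were 11 and none. Outside the list, the model AMEX60DD049493, annotated as both MMP3/10A and MMP13, had 0 counts in controls and 221 after gentamicin. It was at least 81.5-fold higher against a floor of 3 counts over the group. Which of these metalloproteinases it encodes was not tested. It lies in a cluster of MMP genes on chromosome 7q, 770954416 to 770977908. Macrophage genes rose with this list.

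Genes of energy metabolism fell, together with the proximal tubule list. Of 37 tested fatty acid oxidation genes 26 fell and 1, CPT1A, rose (27 and 1 adjusted over the list alone), with a median log2 fold change of -0.69 (camera adjusted p = 5.3e-13; adjusted p = 0.113 with an estimated correlation). CPT1A was not called with gentamicin 1 or gentamicin 3 left out. The carnitine carrier SLC25A20 fell 17.1-fold, the peroxisomal enzyme EHHADH 10.7-fold, and ACAA2 from 532 ± 48.8 to 124 ± 4.03 CPM. Of 45 oxidative phosphorylation genes 40 fell and none rose (42 and 0 adjusted over the list alone), with a median log2 fold change of -0.73 (camera adjusted p = 1.17e-10; adjusted p = 0.113 with an estimated correlation). SDHB fell 2.38-fold and SDHA 1.95-fold. Cholesterol synthesis had 15 lower and no higher genes of 20 (18 and 0 adjusted over the list alone; median log2 -0.89; camera adjusted p = 3.63e-07; adjusted p = 0.234 with an estimated correlation). LSS fell 4.58-fold and HMGCS1 2.71-fold. Without control 3 the number of higher cholesterol synthesis genes was 1.

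Genes that NRF2 controls in oxidative stress were lower on balance. Of 31 tested genes 15 fell and 3 rose (17 and 3 adjusted over the list alone), with a median log2 fold change of -0.77 (camera adjusted p = 2.72e-05; adjusted p = 0.113 with an estimated correlation). The export pump ABCC2 fell 20.6-fold and the catalase models named CAT 5.32- and 9.96-fold, the larger from 3092 ± 697 to 310 ± 20.3 CPM. The proximal tubule list fell with this list, by a median of -3.43. TKT and 2 FTH1 models on an unplaced contig rose, and the number of higher genes was 1 without gentamicin 3. FTH1 AMEX60DD004586 fell 3.06-fold, from 3435 ± 228 to 1121 ± 73.8 CPM, and reads shared between FTH1 copies leave each copy's level uncertain. Lysosome genes were not called as a list (8 higher and 8 lower of 42, 8 and 11 adjusted over the list alone; median log2 0.06; camera adjusted p = 0.687). ASAH1 rose 3.08-fold, the protease CTSL 2.45-fold and the autophagy receptor SQSTM1 2.31-fold, and LAMP2 fell 2.93-fold. Without gentamicin 1 there were 5 higher and 5 lower lysosome genes, and without gentamicin 3 there were 4 lower. Genes of the unfolded protein response had 2 higher and 3 lower of 29, also adjusted over the list alone (median log2 0.06; camera adjusted p = 0.702). DDIT3, or CHOP, rose 7.45-fold, while ATF4 rose 1.36-fold in a call lost when control 1, 2 or 3 or gentamicin 1 was left out. HERPUD1, DNAJB9 and ASNS fell, and the number of lower genes was 0 without gentamicin 1 and 1 without gentamicin 3. Ribosomal protein genes had 15 lower and none higher of 105, and 0 of either adjusted over the list alone (median log2 -0.39; camera adjusted p = 0.00168; adjusted p = 0.693 with an estimated correlation). RPL7 fell 1.54-fold and RPS12 1.66-fold. The number lower was 0 without gentamicin 3, 39 without gentamicin 1, 7 without control 1 and 8 without control 2, and the list was not called without gentamicin 3. The proximal tubule list fell with the ribosomal list too.

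Lists of other tissues checked what else the samples held. Endothelial genes had 1 higher (ROBO4) and 2 lower (FLT1 and PLVAP) of 22 (0 and 1 adjusted over the list alone; median log2 -0.21; camera adjusted p = 0.478). The higher gene was called without control 3 but not with any other library left out, and the lower genes numbered 0 without gentamicin 1 and 1 without gentamicin 3. FLT1 and PLVAP were not called with total-count scaling (edgeR adjusted p = 0.166 and 0.188). Of 28 multiciliated cell genes none was called over all genes or adjusted over the list alone (camera adjusted p = 0.964). Their median log2 fold change of 0.01 and mean of -0.08 differed in sign. DNAH9 had the smallest p of that list (edgeR adjusted p = 0.101, and 0.0112 without a filter). The number of lower multiciliated genes was 1 without control 1 and 1 without a filter. Interrenal and chromaffin genes, of the steroid- and catecholamine-producing cells in the amphibian kidney, had 12 lower and 1 higher of 16 (14 and 1 adjusted over the list alone; median log2 -0.94; camera adjusted p = 0.00322; adjusted p = 0.47 with an estimated correlation). CYP11A1 fell 2.24-fold and TH 2.03-fold, CHGA rose 9.90-fold, and 7 genes were lower without gentamicin 1. The model named CHGA is also annotated as CCER2 and had 2.13 ± 0.70 CPM in controls. The more abundant chromogranin gene CHGB fell 2.2-fold, from 202 ± 30.7 to 91.6 ± 5.95 CPM (edgeR adjusted p = 0.000994). The proximal tubule list fell with the interrenal list. The list of liver genes had 6 lower and 2 higher of 13 (7 and 3 adjusted over the list alone; median log2 -2.52; camera adjusted p = 8.78e-07; adjusted p = 0.113 with an estimated correlation). APOB fell 49.5-fold from 1332 ± 96.5 CPM and F2 fell 23.0-fold, while HPX and C9 rose, and the number of higher genes was 1 without gentamicin 3. The proximal tubule list fell with this list. Albumin, ALB, also chosen after its values were seen, stood near the floor in both groups (0.434 and 0.286 CPM). Skeletal muscle and germ cell lists had 3 and 1 tested genes and were too small for the list test: no muscle gene was called (CKM, edgeR adjusted p = 0.408), and the egg coat gene ZP2 fell 17.6-fold from 5.46 ± 1.53 CPM.

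**Figure D2:**
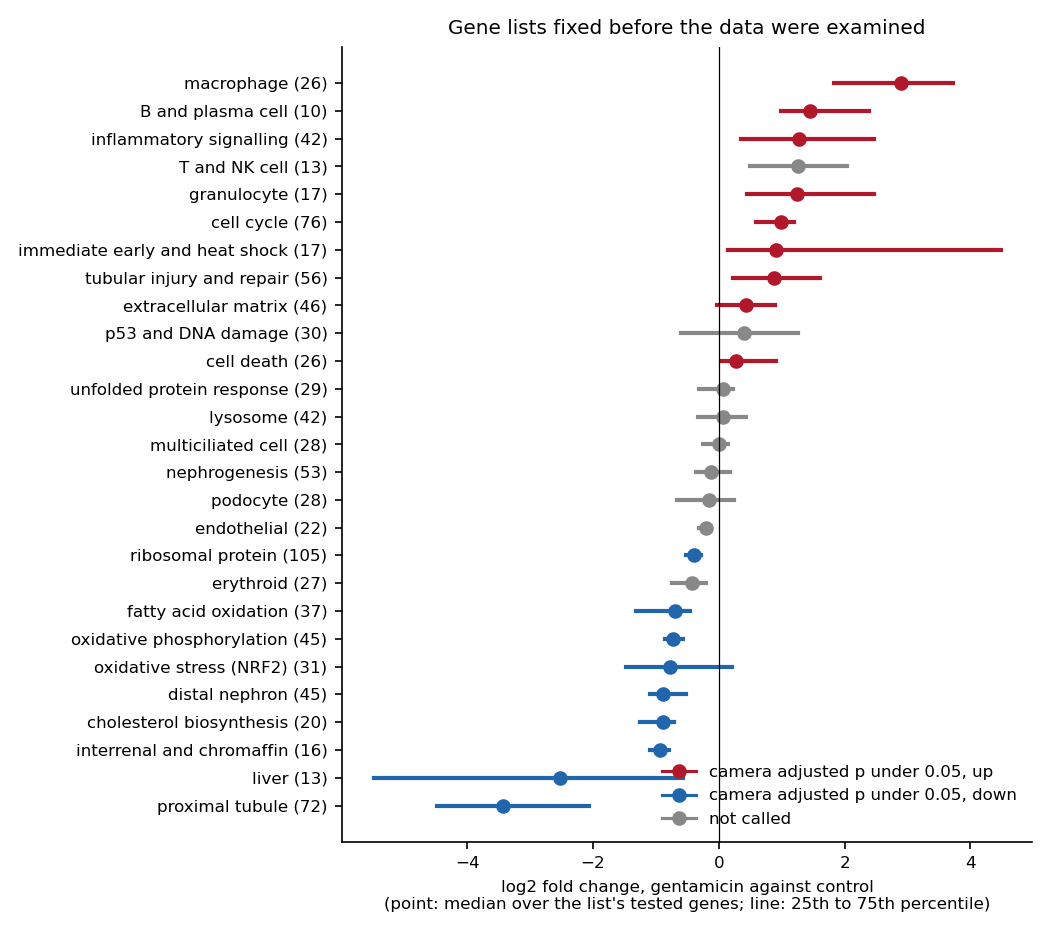
Median log2 fold change of gentamicin against control (points) and 25th to 75th percentile (lines) for the 27 gene lists with at least 5 tested genes, with the number of tested genes in brackets. Red lists were called up and blue lists called down by camera with its preset correlation; proximal tubule genes stand lowest at -3.43 and macrophage genes highest at 2.89, and none of the 18 calls held with an estimated correlation.

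In all, 18 of the 27 lists with at least 5 tested genes were called by camera with its preset correlation of 0.01, 9 up and 9 down. With the correlation estimated from the residuals, which have 3 degrees of freedom, camera called 0 lists (smallest adjusted p = 0.113), and 8 lists had an unadjusted p under 0.05. The NRF2 and cell death lists lost their calls too (camera adjusted p = 0.113 and 0.141). Their estimated correlations, -0.002 and -0.011, lay below the preset 0.01. The loss of the calls therefore does not by itself show that correlation between genes had produced them. The fry test called 18, of which 17 were shared. With total-count scaling the median log2 fold changes of the podocyte, nephron formation and endothelial lists were 0.17, 0.19 and 0.11, above 0 instead of below. The numbers of lower genes were then 24 for oxidative phosphorylation, 17 for fatty acid oxidation, 7 for the interrenal list, 5 for lysosomes, 4 for nephron formation, 2 each for p53 and inflammatory signalling, 1 each for ribosomal proteins, the matrix and tubular injury, and 0 for the unfolded protein response and endothelium. Higher genes numbered 35 for tubular injury, 19 for lysosomes, 9 each for T and NK cells, the unfolded protein response and nephron formation, 8 for podocytes, 7 for the distal nephron, 6 for NRF2, 5 for erythroid genes, 4 for multiciliated cells, 3 for endothelium and 1 for ribosomal proteins. Every other list count stayed within 1.5 times of its value with TMM. Some calls of single genes named above and followed under the alternatives were lost beyond those given with them. ASNS, DNAJB9 and RPL7 were not called with total-count scaling. With the replicate number as a block ATF4, CUBN AMEX60DD022110, EPOR, PLVAP, PRF1 and ROBO4 were not called. On filtered FPKM, ATF4, CD3G, PLVAP, PRF1 and ROBO4 were not called with at least 1 of the 2 pseudocounts. On unfiltered FPKM, ATF4, CD3G, CD79B, EPOR, LCK, PLVAP, PRF1 and ROBO4 were not called.

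Several of the genes with the largest decreases by the fixed rule lay outside the lists. TMLHE, which starts carnitine synthesis, fell from 601 ± 99.8 to 1.58 ± 1.64 CPM (edgeR adjusted p = 0.0016), and the gene named ADIF2 from 4694 ± 138 to 20.6 ± 10.9 CPM (edgeR adjusted p = 3.61e-05). DHDH fell 102-fold from 2597 ± 350 CPM and SLC2A11 140-fold from 102 ± 25.3 CPM. CYP2A13 fell 210-fold and UGT2A1 154-fold, both members of large families in which reads may be shared. The organic anion transporters SLCO1A2 and SLCO1C1 are neighbours on chromosome 12p with the same caveat. SLCO1A2 fell 124-fold from 441 ± 147 CPM, and SLCO1C1 had 191 counts in controls and 1 after gentamicin (ratio 173; 95% counting interval 30.6 to 6852) and was not called on unfiltered FPKM. PRLHR, a peptide receptor, was among the largest increases, with 3 counts in controls and 182 after gentamicin (ratio 67.1; 95% counting interval 22.6 to 328.6).

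**Figure D3:**
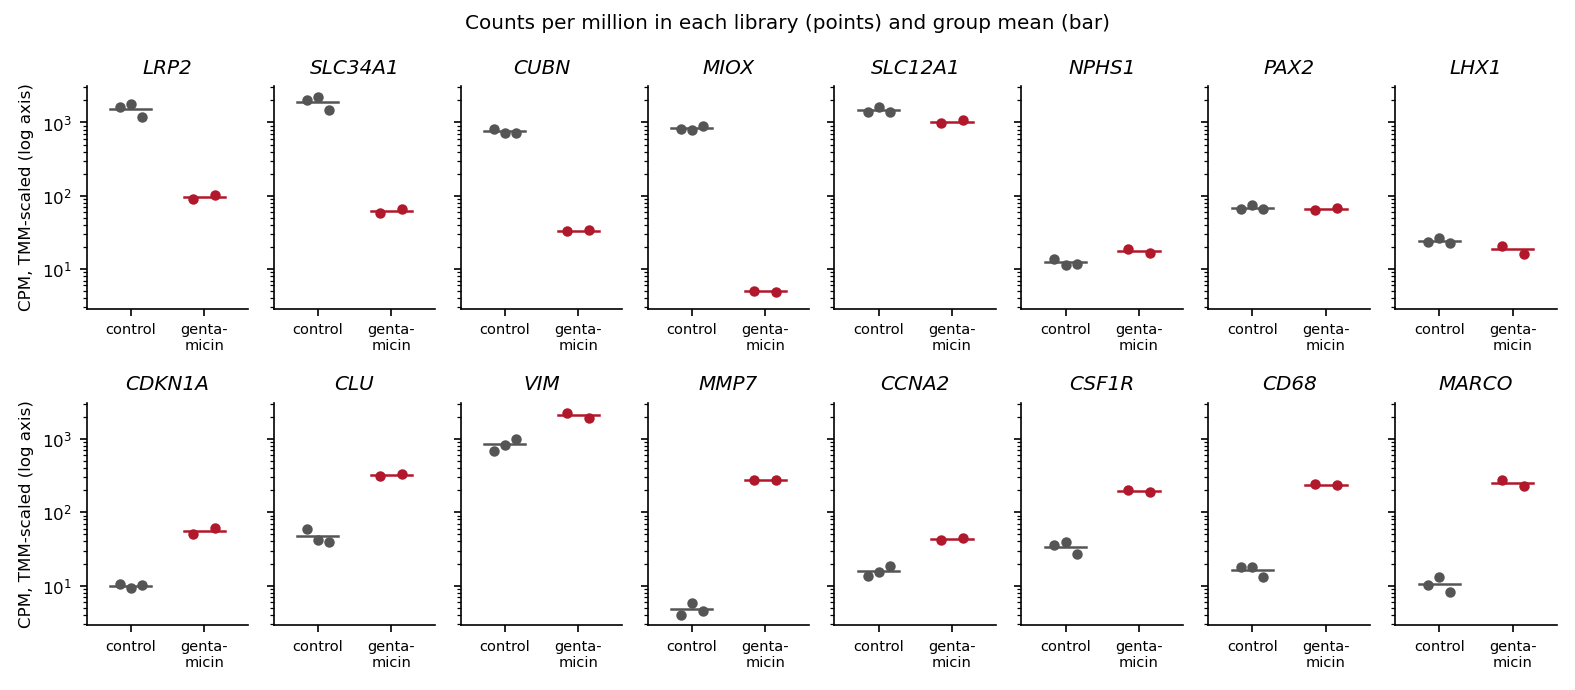
TMM-scaled CPM (vertical axis, log scale) of 16 named genes in each of the 3 control and 2 gentamicin libraries (points), with group means (bars). LRP2, SLC34A1, CUBN (AMEX60DD022111) and MIOX were lower in both gentamicin libraries than in every control, MMP7, CLU, CDKN1A, CSF1R, CD68 and MARCO were higher in both, and PAX2 and LHX1 did not pass the test.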

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

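No alternative called a gene in the direction opposite to the TMM-scaled edgeR test. Between 2289 and 3614 genes were higher and between 2544 and 3568 lower under the alternatives other than those named next and the block. With total-count scaling 6192 were higher and 1895 lower, since the median of all genes shifted by 0.32 (log2). On log2(FPKM + 1) without a filter 1796 were higher and 1828 lower; the cause was not tested. Requiring at least a 2-fold change left 1636 and 1705 by construction. With 1 library left out, between 1333 and 2770 genes were higher and between 1627 and 2963 lower, the fewest with a gentamicin library left out, where the lone library was assumed to vary like the controls. DESeq2 gave no adjusted p for 16387 genes with counts. With an estimated correlation camera called 0 of the 18 lists, and 8 had an unadjusted p under 0.05; the calls held under the other scalings and filters, fry lost the ribosomal list and gained p53, no filter gained p53 and T and NK cells, and leaving out each library gave 18 to 19 called lists. The first component carried 78.7% of the variance on log2(FPKM + 1) against 69.3%; the cause was not tested. The label numbers 1 and 3 occur in both groups but name different animals. Deviations from the group means correlated at -0.036 for number 1 and 0.062 for number 3, and with the replicate number as a block 2118 genes were higher and 2367 lower, with 19 called lists, T and NK cells added.

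Of the 148 named gene models 130 were called, and 22 of these lost the call without at least 1 library. Of 2484 values under alternatives, 2372 kept direction and call, 85 kept the direction below the threshold, 13 passed it newly, and 14 turned direction, all of these in genes that were not called; the cause was not tested. The turned log2 fold changes were, with total counts, 0.12 for COL1A1, 0.105 for MKI67 AMEX60DD028336, 0.254 for PAX2 and 0.075 for WT1; with the block, -0.128 for EYA1 and 0.005 for PAX2; with limma-voom, -0.661 for EYA1 and -0.041 for SIX2. With 1 library left out the log2 fold change ranged from -2.413 to 0.923 for EYA1 (below 0 without control 1, -0.341, and gentamicin 1), from -0.035 to 0.134 for UMOD AMEX60DD005630 (below 0 without control 1), from -0.354 to 0.113 for COL1A1 and -0.158 to 0.419 for SIX2 (turned without control 3), and from -0.181 to 0.751 for ACTA2 (below 0 without gentamicin 1). EYA1 and SIX2 had under 1 CPM in both groups, where a small change lies near the floor of 0.183 to 0.219 CPM.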

Other observations

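The gene families and the tests described here were chosen after the results had been seen, as were the single genes that the fixed rule had not taken. The total-count and left-out-library fits that these tests use were among the alternatives fixed beforehand. Families were formed from the stems of gene symbols, 215 of them with at least 10 tested genes. Camera with its preset correlation called 17 up and 15 down, and with an estimated correlation 0 (smallest adjusted p = 0.438). Toll-like receptors, which sense microbial and cell debris, had 11 higher and 2 lower of 15 genes (median log2 fold change 2.32, camera adjusted p = 2.57e-06), interferon regulatory factors 9 higher and none lower of 15 (0.81, 7.04e-05), and the PARP family 12 higher and none lower of 20 (0.96, camera adjusted p = 0.000706). Of single genes outside these families, B2M, the light chain of MHC class I, rose 7.01-fold to 1197 CPM, the peptide-loading factor TAPBP 3.79-fold, OASL 6.24-fold, IFIT5 6.37-fold and HERC6 25.7-fold. The macrophage list moved with them, by a median of 2.89. Cytochrome P450 genes had 42 lower and 3 higher of 69 (median -1.23, camera adjusted p = 1.07e-14) and hydroxysteroid dehydrogenases 15 lower and none higher of 21 (-1.31, 2.04e-11). CYP27B1, which activates vitamin D in the proximal tubule, fell 28.4-fold from 479 CPM, and the cation exporter SLC47A1 fell 26.5-fold in its abundant model. These family medians all exceed in size the shift of 0.32 that total-count scaling makes. SLURP1L rose 28.8-fold, from 39.1 to 1125 CPM.

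Copies of the ferritin heavy chain gene FTH1 moved apart. AMEX60DD016343 on chromosome 1p and AMEX60DD004586 on 11q fell from 25050 ± 5803 to 6992 ± 29.4 CPM and from 3435 ± 228 to 1121 ± 73.8 CPM. AMEX60DDU001033599, on an unplaced contig, rose 7.85-fold from 19.5 ± 9.74 to 153 ± 13.0 CPM (edgeR adjusted p = 0.00602). Its neighbour AMEX60DDU001033597 rose 8.08-fold from 0.462 CPM, and AMEX60DD016342 on 1p stood at 11790 ± 4783 and 3154 ± 1744 CPM (edgeR adjusted p = 0.0525). How reads were divided among the copies was not tested.

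The fall of proximal tubule genes, by a median of -3.43 with the 75th percentile at -2.06, is not explained as a whole by dilution through incoming cells, which would lower other resident cell types alike: the medians were -0.21 for endothelial, -0.15 for podocyte, 0.01 for multiciliated, -0.88 for distal nephron and, lowest, -0.94 for interrenal and chromaffin genes. A smaller share of proximal tubule cells with every other type unchanged would raise other markers together. The macrophage and endothelial medians differed by 3.10, more than the interquartile range of either list (up to 1.90). Both medians were known when this comparison was chosen, and it speaks only against macrophages being unchanged. It does not speak against a smaller share of proximal tubule cells. The choice between TMM and total-count scaling does not account for the fall. It shifted the median of all genes by 0.32, and 61 proximal tubule genes were called lower with total counts. A shift so small beside a median of -3.43 could not end most of these calls, so their number is no evidence of its own. Loss of proximal tubule cells and lower expression per cell, with or without more macrophages, cannot be told apart from whole-tissue counts. The called genes fell by different amounts, with an interquartile range of 2.22 on the log2 scale, but expression in other segments could spread them in the same way.

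The rise of macrophage genes was not matched by the erythroid genes as a set. The 75th percentile of the erythroid genes was -0.20 and the 25th percentile of the macrophage genes 1.83. Of 27 erythroid genes 3 were higher and 3 lower, and the alpha globin model HBA1 had 0 control counts. Since erythroid genes do not follow white blood cells, blood left in the tissue is not excluded. More macrophages in the injured kidney may account for the median of 2.89, as a hypothesis, but higher expression per cell cannot be told apart from it in whole-tissue counts.

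Of the immediate early and heat shock genes, 9 were called higher. A single unusual library is argued against, since at least 7 genes of the list were called higher with either gentamicin library left out. A difference in handling at collection remains open for these 9 genes, since the labels do not say how either group was handled; the response to injury that the groups name remains open too. The groups were also compared with the other splits of the 5 libraries into 3 and 2. Of the 10 splits only 1, the real one, called as many as 5890 genes, and the highest of the others called 0, but so few splits cannot give a share under 0.05. Every other split also puts control and gentamicin libraries in the same group. This widens the spread within that group, so the 0 calls there are no evidence of their own.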
